A study of Cynodon dactylon with 10 samples.

How the data were processed

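RNA from leaves of bermudagrass seedlings was measured in 10 libraries, 2 each for the control and for drought, salt, submergence and heat. Per the labels' protocols, total RNA was isolated with the Qiagen RNeasy kit and libraries were made by Illumina's protocols. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0, without saying what each was used for. The assembly behind the contigs and its build are not given in the sources used here. The deposited values are RPKM, per the file headers, in 1 column per library with 2 decimals. The file is named for read counts, but its values are not whole numbers, and they were treated as RPKM.

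The design fixed before the data were examined assumed read counts. Because the values are RPKM, a linear model on log values was used in place of the count model, and the tests that need counts were left out. Libraries were scaled by a trimmed mean of log ratios, without the precision weights that need counts, trimming 30% of the ratios and 5% of the mean levels at each end. Contigs with at least 1 RPKM in at least 2 libraries were tested. That kept 26884 of 28456 contigs and left out 1572, of which 227 were at 0 in every library. Scaled values were taken to log2(RPKM + 1), so a fold change is on that scale and understates the change of low contigs. The model had the group as its only term, used all 10 libraries with 5 residual degrees of freedom, and was fitted with limma 3.58.1 in R 4.3.3, with a variance trend. Adjusted p-values are Benjamini-Hochberg values per comparison, and a contig was called at an adjusted p under 0.05. Where a size is stated, calls also needed a fold change of at least 2 or 8. Each stress was compared with the control, and the 6 pairs of stresses were compared in the same fit. Library distances used log2(RPKM + 2). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the depth and the figures.

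Absolute depth is unknown. Relative depth came from the steps between low RPKM values, which are whole multiples of what 1 read is worth. Depth ratios taken directly between the other libraries were compared with those taken through control replicate 1, and 35 of 36 pairs differed by under 2%, with a median difference of 0.598%. Among contigs of at least 500 RPKM, the robust SD of the log2 ratio between replicates was 0.0391 to 0.0778. The value expected if only counting noise were present, scaled from contigs of 20 to 50 RPKM, was 0.0145 to 0.0192. The 2 libraries of a group thus differed by more than counting noise, which argues against 1 library deposited under 2 names. They were counted as 2 libraries, and the spread does not show whether they came from separate plants.

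The fit was tested on simulated data with 26884 contigs per comparison. A log2 change of 0.5 was recovered for 70.1% of changed contigs in the simulated drought comparison, 65.7% for salt, 59.7% for submergence and 59.7% for heat. A log2 change of 1 was recovered for 77.6%, 76.1%, 71.6% and 73.1% in that order, and one of 2 for 98.5%, 98.5%, 100% and 98.5%. False calls were 7.87%, 6.98%, 6.67% and 6.10% of the calls, each above the nominal level of 0.05. Far fewer contigs changed there than were called in the data, so these shares need not hold for the data.

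Contigs were named by a rule: of those called in all 4 comparisons in one direction, the 2 rising and the 2 falling with the largest smallest change. The files do not pair the identifiers with gene names, so no further contig is named, and none of the 36 gene lists fixed beforehand could be matched or tested. Contigs that share an identifier up to the last part are called siblings of one subcomponent. Reads may be split between siblings, so their single values are uncertain. Alternatives covered scaling, the filter, the threshold, the libraries in the fit, a replicate block and leaving out each library. Those for the pseudocount, a control library for each stress, a group-mean filter, 1 contig per subcomponent, the variance trend, and leaving out contigs or libraries tied to submergence were chosen after seeing the data.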

Results

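Bermudagrass (Cynodon dactylon), a perennial turf and forage grass, was grown as seedlings to 3 weeks of age and then kept for 7 days under 1 of 4 stresses or left unstressed. Water was withheld for drought, 400 mM NaCl was given for salt, seedlings were put under water for submergence, and the temperature was set at 42 °C for heat. Leaf RNA was sequenced, with 2 libraries for the control and for each stress, 10 in all. Abundance was given in RPKM, read density normalised to contig length and library size, for 28456 assembled contigs, which carry assembly identifiers and no gene names. The total per library ran from 751923 to 795078 RPKM, and 23755 to 25948 contigs reached 1 RPKM. The read totals are unknown. The steps between low values put the depth of the libraries, relative to control replicate 1, between 0.791 in heat replicate 2 and 1.01 in salt replicate 2. The labels do not say whether the 2 libraries of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

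Replicates lay closer to each other than to any other group. The root mean square difference in log2 RPKM between the 2 libraries of a group was 0.156 to 0.183. Salt-treated leaves were nearest to the control, at 0.320, followed by drought at 0.765, heat at 1.06 and submergence at 1.32. Drought and heat lay 0.818 apart. The smallest distance between libraries of different groups was 1.73 times the largest distance between replicates. Among contigs of at least 100 RPKM, the robust SD of the log2 ratio between replicates ran from 0.0454 under heat to 0.0751 under drought.

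**Figure D1:**
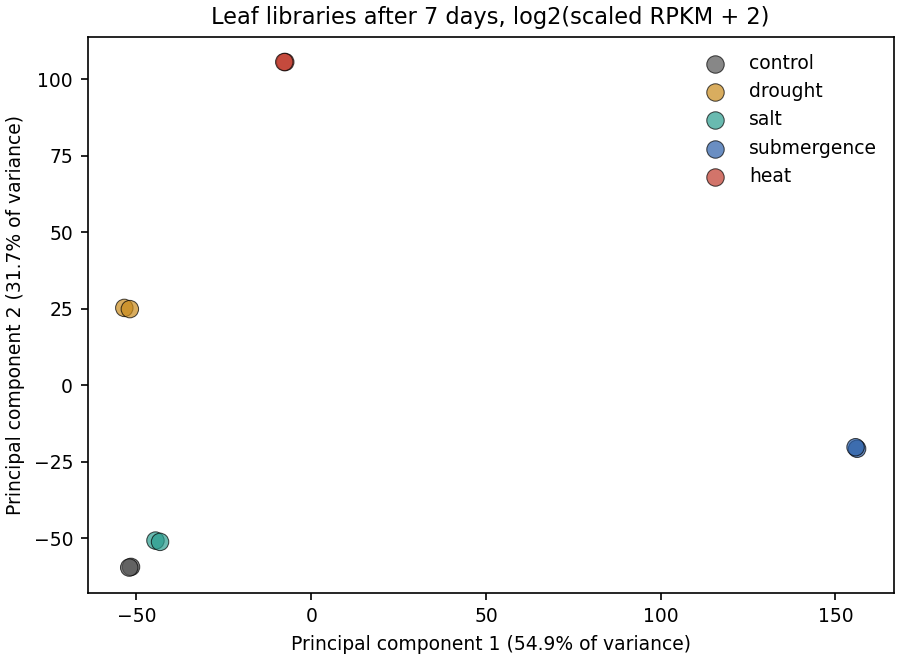
Principal components of log2 RPKM for the 10 libraries, with each point 1 library and each colour 1 group. The first component holds 54.9% of the variance and the second 31.7%, and the 2 libraries of each group lie side by side.

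Fewer contigs were listed at 0 in submerged leaves, and the transcriptome was less dominated by its most abundant members under 3 of the stresses. They numbered 562 ± 28.3 under submergence (SD, n = 2), against 2543 ± 86.3 in the control, 2840 ± 39.6 under drought, 2173 ± 12.7 under salt and 2886.5 ± 53.0 under heat (SD, n = 2 each). A fixed list of the 100 contigs with the highest mean RPKM over all libraries held 23.7% ± 0.278 of all RPKM in the control and 22.3% ± 0.115 under salt (SD, n = 2 each). Their share was 14.7% ± 0.476 under drought, 15.7% ± 0.0111 under heat and 12.4% ± 0.218 under submergence (SD, n = 2 each). The 100 most abundant contigs of each library, which need not be the same contigs, held 25.05% ± 0.231 in the control, 23.2% ± 0.188 under salt, 17.2% ± 0.530 under drought, 17.7% ± 0.0115 under heat and 16.6% ± 0.168 under submergence (SD, n = 2 each). Of the fixed list, 45 fell at least 2-fold under drought, 59 under submergence and 56 under heat. Their median log2 change was -0.61 under drought, -2.06 under submergence, -1.17 under heat and -0.17 under salt. Without scaling, 44, 56 and 46 of them fell at least 2-fold under drought, submergence and heat.

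The first question was what 7 days without water changed in the leaf. Drought raised 1911 contigs at least 2-fold and lowered 2160, out of 26884 tested. A rise of at least 8-fold was seen for 208 contigs and a fall of that size for 93. From under 0.5 RPKM in the control, 49 contigs reached at least 5 RPKM under drought, and 29 went the other way. Of the 141 contigs with a mean of at least 500 RPKM, 61 fell and 11 rose at least 2-fold, with a median log2 change of -0.50. Of the 2677 contigs with a mean of 50 to 500 RPKM, 241 fell and 320 rose, with a median of 0.16. Without the size limit, limma called 16376 contigs at an adjusted p under 0.05, of which 8259 were higher and 8117 lower. The balance depended on the scaling: median-ratio scaling gave 7956 higher and 8366 lower, upper-quartile scaling 7147 and 9162, and no scaling 9348 and 7105. At 2-fold, no scaling gave 2109 higher and 1890 lower.

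Salt gave the smallest response of the 4 stresses. It raised 366 contigs at least 2-fold and lowered 86, and with a pseudocount of 0.1 RPKM in place of 1 these counts were 718 and 157. Of the 366, 140 were also raised at least 8-fold by submergence, and their salt level had a median of 4.73% of their submergence level. These 140 had a median of 0.488 RPKM in the control, 4.21 under salt and 86.1 under submergence. Limma called 6969 contigs without the size limit, 3686 higher and 3283 lower. With the values as deposited, without scaling, the split moved to 5215 higher and 2074 lower. The count was 4614 without control replicate 1 and 4281 when only the control and salt libraries entered the fit.

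Submergence changed more contigs at least 2-fold than the other stresses did with all libraries in the fit. It raised 4428 contigs at least 2-fold and lowered 4294, and 1213 rose and 581 fell at least 8-fold. From under 0.5 RPKM in the control, 1204 contigs reached at least 5 RPKM, and 140 went the other way. A set of 903 contigs had at least 5 RPKM under submergence and under 0.5 RPKM in each of the other 4 groups, with a median of 13.7 RPKM in submerged leaves. This set held 3.14% ± 0.00355 of the RPKM under submergence and 0.0106% ± 0.000162 under salt, the highest of the other groups (SD, n = 2 each). All 903 were among the contigs raised at least 2-fold, 20.4% of them. Without the set, 3525 contigs rose and 4294 fell at least 2-fold. Fold changes of unscaled group means with 0.05 RPKM added to each, unlike those of the fit, gave a larger set of 1208 contigs. They were raised over 45.3-fold on that scale by submergence, to at least 5 RPKM. They held 8.56% and 8.49% of the RPKM in the 2 submergence libraries. With these left out, 7514 contigs changed at least 2-fold under submergence, 3220 higher and 4294 lower. Heat then changed 7453, 3204 higher and 4249 lower. The set was chosen by its rise under submergence, and no such set was left out for heat. Leaving it out lowers the submergence count by construction, so these counts do not rank the 2 stresses. Of the 141 contigs with a mean of at least 500 RPKM, 83 fell and 11 rose at least 2-fold, and of the 2677 with a mean of 50 to 500 RPKM, 800 fell and 304 rose. Of the 17337 with a mean of 5 to 50 RPKM, 2702 fell and 2162 rose, and of the 6729 with a mean under 5 RPKM, 709 fell and 1951 rose.

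In all, limma called 20330 contigs under submergence, 11232 higher and 9098 lower, with a median log2 change of 0.10 over the contigs tested. Without scaling this median was 0.33, and 14371 were called higher and 7055 lower. At 2-fold the unscaled values gave 5606 higher and 3427 lower, and upper-quartile scaling gave 4299 higher and 4415 lower.

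**Figure D2:**
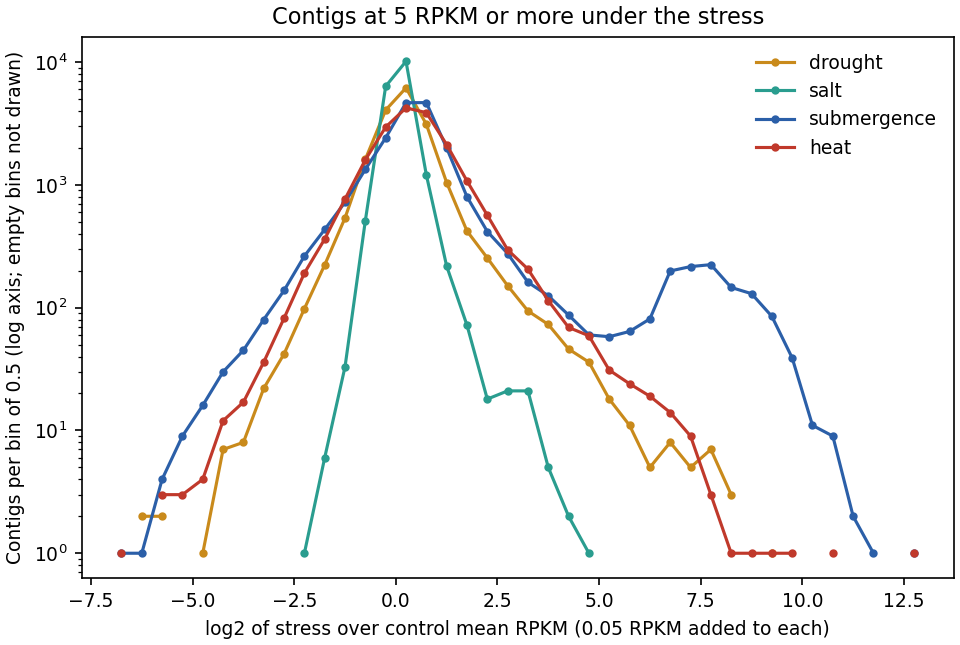
Distribution of the log2 ratio of stress over control mean RPKM, with 0.05 RPKM added to each, for contigs of at least 5 RPKM under the stress. The horizontal axis is log2 fold, the vertical axis is contigs per bin on a log scale, and each line is 1 stress. Under submergence 224 contigs lie between 7.5 and 8, above a low of 58 contigs in the bin that starts at 5.

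Heat lowered more contigs than it raised at 2-fold. It raised 3267 and lowered 4258, and 290 rose and 479 fell at least 8-fold. From under 0.5 RPKM in the control, 84 contigs reached at least 5 RPKM, while 234 went from at least 5 to under 0.5 RPKM. Of the 141 contigs with a mean of at least 500 RPKM, 77 fell and 15 rose at least 2-fold, and of the 2677 with a mean of 50 to 500 RPKM, 636 fell and 378 rose. Limma called 19332 contigs, 9523 higher and 9809 lower. Here too the balance depended on the scaling: without it, 11991 were higher and 7805 lower, and at 2-fold 4461 were higher and 3384 lower.

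**Figure D3:**
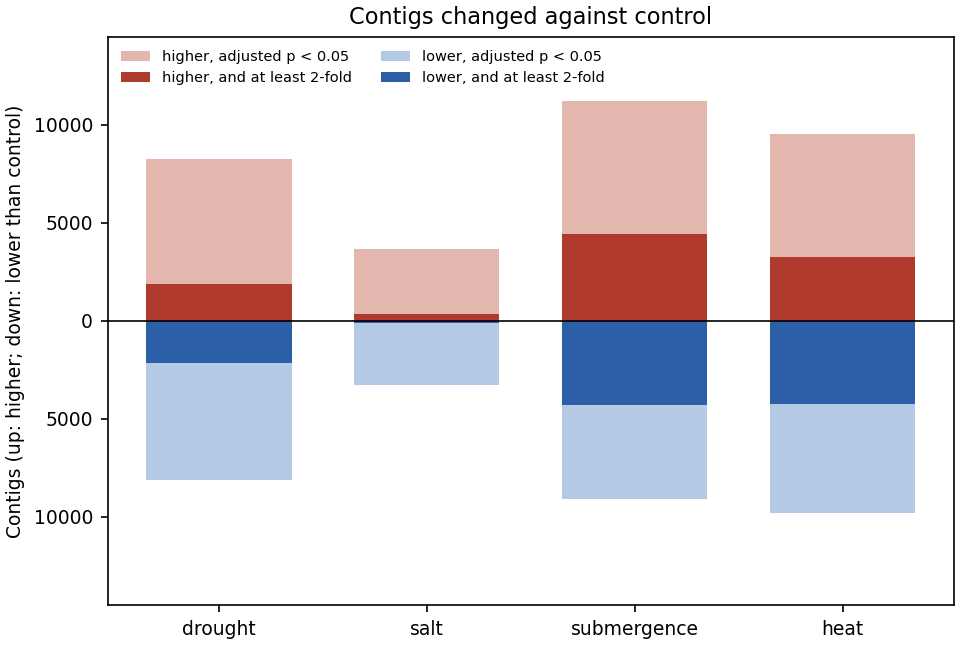
Contigs called against the control for each stress, with higher contigs above 0 and lower contigs below it. Pale bars count contigs at an adjusted p under 0.05, and dark bars those also changed at least 2-fold, which number 452 under salt and 8722 under submergence.

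The stresses were also compared with each other in the same fit. Submerged leaves differed at least 2-fold from droughted leaves in 9027 contigs, from heated leaves in 8666 and from salt-treated leaves in 8365. Heated leaves differed from salt-treated leaves in 7144 contigs and from droughted leaves in 5351, and salt-treated from droughted leaves in 3435. Without the size limit, the count of contigs that differed was 20687 for submergence against drought, 20491 for heat against submergence and 20287 for submergence against salt. It was 19521 for heat against salt, 18177 for heat against drought and 15299 for salt against drought. For heat against drought, 2169 contigs were higher and 3182 lower at 2-fold, and 2914 and 2630 without scaling.

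Contigs that differed at least 2-fold in one direction from the control and from each of the other 3 stresses were counted as particular to a stress. Submergence had 2663 such contigs that were higher, or 1760 without the 903 contigs abundant only under submergence, and 1494 that were lower. Heat had 627 higher and 838 lower, and drought had 331 higher and 122 lower. Salt had 40 that were higher and 2 that were lower, which are not named because the files give no gene names.

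Drought and heat shared many of their changes. At 2-fold, 1196 contigs rose and 1475 fell under both, where independent lists would share 232 and 342. Of these 2671 contigs, 1412 differed between the stresses with the larger change under heat, and 478 with the larger change under drought. Submergence and heat shared 1192 rises and 2239 falls, against 538 and 680 for independent lists. Drought and submergence shared 665 rises and 975 falls, against 315 and 345. Drought and salt shared 159 rises and 51 falls, against 26.0 and 6.91, and 176 of these 210 contigs changed more under drought. Salt and submergence shared 202 rises and 48 falls, against 60.3 and 13.7, and 222 of these 250 changed more under submergence. Among the 202 rises are the 140 contigs raised at least 8-fold by submergence, for which RNA of another organism stays open, as described below. Salt and heat shared 129 rises and 59 falls, against 44.5 and 13.6. In 100 simulations, all 10 libraries were redrawn around the control means, with normal noise and no group difference. Limma called at most 2 contigs in a comparison there. Calls are rare in such draws by construction, so they do not show how much the real control libraries add to the overlaps. Each comparison shares the 2 control libraries with the others, and part of the excess may come from them. With 1 control library for each stress of a pair, taken both ways, drought and heat shared 1195 and 1169 rises and 1421 and 1457 falls. Salt and submergence then shared 200 and 203 rises, and drought and salt 158 and 160.

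Across contigs, which are not independent replicates, the log2 fold changes of drought and heat had a Pearson's r of 0.643. The value was 0.479 for drought and salt, 0.410 for submergence and heat, 0.335 for salt and submergence, 0.299 for salt and heat and 0.229 for drought and submergence. Unchanged groups simulated with shared, redrawn controls gave an r of 0.497 to 0.501, so the covariance was compared instead. The simulated covariance was 0.0113 to 0.0115. The observed covariance was 0.729 for submergence and heat, 0.635 for drought and heat, 0.291 for drought and submergence, 0.173 for salt and submergence, 0.137 for drought and salt and 0.120 for salt and heat. With 1 control library for each stress, r was 0.625 for drought and heat, 0.418 for drought and salt, 0.401 for submergence and heat, 0.299 for salt and submergence, 0.258 for salt and heat and 0.219 for drought and submergence, as means of both ways. In 20 simulations of unchanged groups without shared controls, r ran from -0.0648 to 0.0611.

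A set of 81 contigs changed at least 2-fold in one direction under all 4 stresses, 58 of them rising and 23 falling. Independent lists would give 0.521 and 0.175. The median absolute log2 change of the 81 was 3.32 under heat, 3.08 under drought, 2.71 under submergence and 1.25 under salt, and salt gave the smallest change in 64. Without the size limit, 1289 contigs were higher and 1255 lower under all 4, where independent lists would give 168 and 122. Without scaling 2171 were higher and 734 lower. The total of 2544 was 1583 when only the 2 groups compared entered each fit, with 638 higher and 945 lower.

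Of the contigs that rose under all 4 stresses, 2 were taken by their smallest change over the stresses. comp53504_c1_seq1 went from 29.4 ± 1.25 RPKM in the control to 588 ± 20.3 under drought, 120.02 ± 1.57 under salt, 251.57 ± 3.15 under submergence and 1161 ± 23.7 under heat (SD, n = 2 each). Its log2 changes were 4.20, 1.91, 2.79 and 5.02 in that order, each with an SE of 0.04. comp19989_c0_seq1 went from 15.4 ± 0.552 RPKM to 798 ± 2.48 under drought, 61.4 ± 3.59 under salt, 419 ± 5.94 under submergence and 1479 ± 2.21 under heat (SD, n = 2 each). Its log2 changes were 5.53, 1.85, 4.42 and 6.27.

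The 2 falling contigs were chosen in the same way. comp57580_c3_seq5 had 43.3 ± 2.64 RPKM in the control, 9.24 ± 1.36 under drought, 11.7 ± 1.57 under salt, 3.10 ± 0.403 under submergence and 1.57 ± 0.502 under heat (SD, n = 2 each). Its log2 changes were -2.20, -1.89, -3.67 and -4.31, each with an SE of 0.16. comp53817_c2_seq1 had 18.4 ± 0.849 RPKM in the control, 5.32 ± 0.120 under drought, 5.06 ± 0.375 under salt, 0.255 ± 0.0212 under submergence and 2.63 ± 0.615 under heat (SD, n = 2 each). Its log2 changes were -1.70, -1.76, -4.10 and -2.63.

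**Figure D4:**
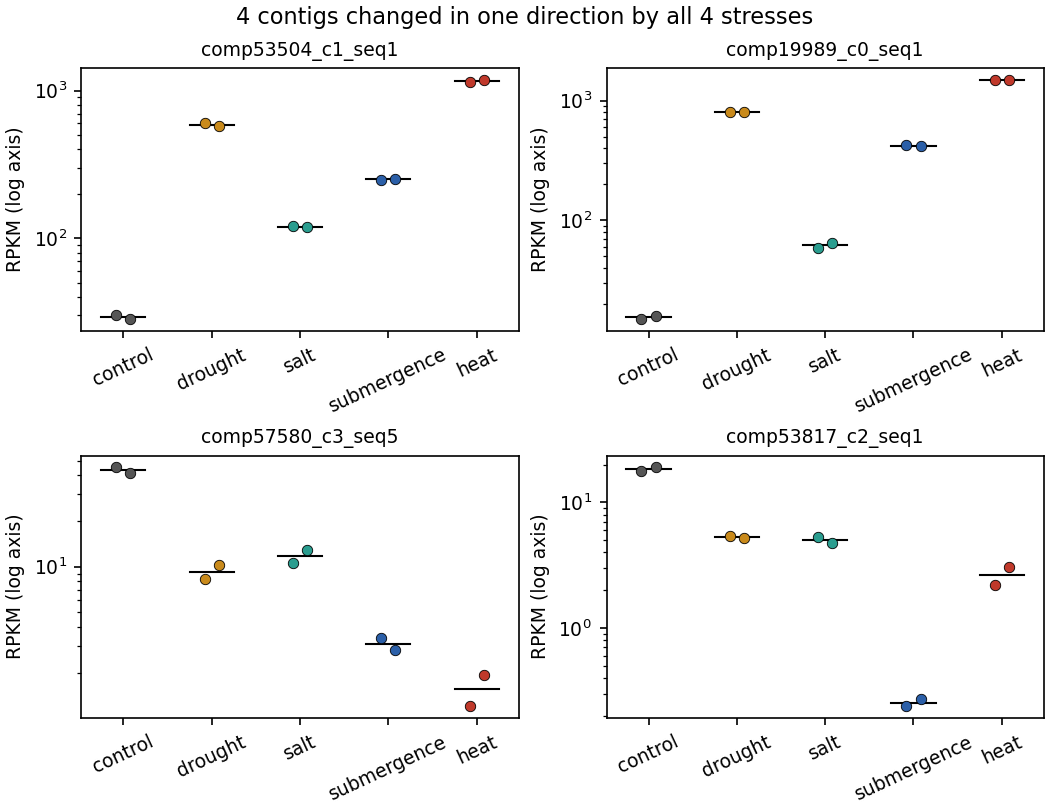
RPKM of the 2 rising and 2 falling contigs in each library, with 1 point per library on a log axis and the groups along the horizontal axis. comp19989_c0_seq1 reaches 1479 RPKM under heat, and comp53817_c2_seq1 drops to 0.255 RPKM under submergence.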

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

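Contigs changed at least 2-fold in opposite directions by 2 stresses are given first, and then 2 patterns in the submergence and salt comparisons. The direct test between the 2 stresses called all such contigs. That outcome was all but fixed by opposite changes in the same fit, so it adds no support. The tests of depth and of a trace in the salt libraries were chosen after the result was seen.

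Drought and submergence moved 476 contigs in opposite directions, 22.5% of the 2116 that both changed at least 2-fold. The count was 396 of 3827 (10.3%) for submergence and heat, 92 of 2763 (3.33%) for drought and heat and 65 of 315 (20.6%) for salt and submergence. It was 55 of 243 (22.6%) for salt and heat and 13 of 223 (5.83%) for drought and salt. In each pair, more of the contigs changed by both moved in one direction than in opposite directions. Counts for independent lists were not computed for opposite changes, so these numbers do not show more of them than independent lists would give.

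The first pattern is the set of 903 contigs abundant only under submergence. Depth argues against a shortfall of reads elsewhere, since the submergence libraries had 0.988 times the depth of the control libraries. A trace of the submergence libraries in the control cannot be told apart from low expression there, because Spearman's rho between control and submergence RPKM across the set was 0.439, between the bounds set for a yes or a no. RNA of another organism in the submerged leaves is a candidate explanation that stays open. Of the set, 28.9% had siblings, against 52.1% of 520 contigs outside it raised at least 8-fold by submergence (Fisher's exact test, two-sided, p = 5.25e-18). The set was chosen by level and the 520 by fold change. The 520 also hold the 140 contigs of the second pattern, whose origin is open too, so they are not a reference of plant contigs alone. Siblings entered the test as separate contigs although they are not independent, so the p-value may be too small. Plant genes that are silent in the other groups remain an open explanation too, and contig sequences were not analysed here.

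The second pattern is the 140 contigs raised at least 2-fold by salt and at least 8-fold by submergence, 38.3% of the salt rises of at least 2-fold. The values argue against a trace of the submergence libraries at 1 ratio. Of the set of 1208 contigs raised over 45.3-fold by submergence, 315 were at 50 RPKM or more there. Among these 315, 27.3% had a salt level of 3.125% to 12.5% of the submergence level, with a median of 4.51%. A further 136 lay in a lower range with a median of 0.455%. RNA of another organism in both treatments may account for the second pattern. Of the 140, 22.1% had siblings, against 53.1% of the 226 other contigs raised by salt, some of which submergence raised by less (Fisher's exact test, two-sided, p = 4.87e-09). Here too siblings entered the test as separate contigs, so the p-value may be too small. A response of plant genes shared by both stresses stays open and was not tested.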

How the results depend on the processing

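The pseudocount of the fit, a control library for each stress, the variance trend, 1 contig per subcomponent, the group-mean filter and the sets left out were chosen after seeing the data. Over all alternatives run, the 6 correlations stayed above 0. Of the values that answer a comparison, 342 stayed within their margin and 68 moved beyond it. The margin was wide for counts and narrow for correlations. For drought, 13237 calls at an adjusted p under 0.01, against 16376, lay within it. A correlation of 0.217 without scaling for drought and submergence, against 0.229, lay beyond it. A count within its margin may hold other contigs: without scaling, 82.6% of the salt calls were kept. The balance of higher against lower calls turned with the scaling, at 2-fold or without a size limit, for drought, submergence and heat against the control and for salt against drought, submergence against salt, heat against drought and heat against salt. Where the counts are close it turned under other alternatives too. The 4 named contigs kept their direction and stayed past the threshold in 364 values over 23 settings, with a highest adjusted p of 0.0109. They were chosen from the same libraries for large changes under all 4 stresses, so this does not show how stable other calls are. The cause of the moves was not tested, except that a size limit or a stricter threshold calls fewer contigs by construction. The count tests, the count filter and the gene lists were not run, because the values are not counts and carry no gene names. Depth limits low contigs most, and the read totals are unknown.

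At 2-fold the counts were 4071 for drought, 452 for salt, 8722 for submergence and 7525 for heat, and 3435, 9027, 5351, 8365, 7144 and 8666 for salt against drought, submergence against drought, heat against drought, submergence against salt, heat against salt and heat against submergence, with 81 for all 4 stresses. With a pseudocount of 0.1, salt gave 875 at 2-fold. At an adjusted p under 0.01, salt gave 3914 and all 4 stresses 1451. With only the 2 groups compared in the fit, they gave 4281 and 1583. Leaving out 1 library at a time, with a lone sample assumed to vary like the other groups, gave 4614 to 6993 for salt, and 4614 was without control replicate 1. The range was 14490 to 16317 for drought, 18546 to 20412 for submergence, 17829 to 19397 for heat (18913 and 18911 against 18578 and 18546 for submergence when a submergence library was left out) and 1781 to 2468 for all 4 stresses. Without scaling, 115 submergence calls and 60 heat calls had the opposite direction. The distance ratio between and within groups was 1.56 with a pseudocount of 0.5.

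The correlation of drought and salt was 0.602 for contigs with a mean log2 of at least 5, and 0.461 and 0.412 with pseudocounts of 0.5 and 0.1. It was 0.522 without the set of 1208 contigs raised over 45.3-fold by submergence, and 0.449 to 0.491 without 1 library. For drought and submergence it was 0.394, 0.213, 0.165, 0.2999 and 0.222 to 0.237 in that order, with 0.244 under upper-quartile scaling, 0.217 without scaling and 0.268 without the 903 contigs. For drought and heat it was 0.662 at that mean, 0.638 with a pseudocount of 0.1, 0.640 without the contigs raised over 45.3-fold and 0.635 to 0.647 without 1 library. For salt and submergence it was 0.383 at that mean, 0.379 with a pseudocount of 0.1, 0.285 without the contigs raised over 45.3-fold, 0.301 without scaling, 0.371 without the 903 contigs and 0.306 to 0.345 without 1 library. For salt and heat it was 0.373, 0.285, 0.250, 0.325 and 0.283 to 0.313 in the order of drought and salt, with 0.286 without scaling. For submergence and heat it was 0.564, 0.386, 0.325, 0.517 and 0.408 to 0.415 in that order, with 0.384 without scaling and 0.467 without the 903 contigs. With 1 control library for each stress, the 6 correlations were 0.418, 0.219, 0.625, 0.299, 0.258 and 0.401 in the order of this paragraph.

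The replicate numbers gave little sign of pairing: the correlations of same-numbered deviations ran from -0.0521 for drought and heat to 0.121 for drought and salt. With 2 libraries per group these values cannot exclude a pairing or a batch. With a replicate block the counts were 16256 for drought, 6650 for salt, 20227 for submergence, 19256 for heat and 2438 for all 4 stresses.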

Other observations

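Contigs of one subcomponent were compared with each other, by a test whose outcome was stated before it was seen. The hypothesis that they change together held in all 4 comparisons: among sibling pairs in which both contigs were called, the share changing in one direction was lowest under heat, at 78.8%. It was 83.6% under drought, 83.5% under submergence and 91.9% under salt. The highest share among 1000 shuffles of contigs over subcomponents was 51.9% under heat, 52.2% under drought, 52.2% under submergence and 56.1% under salt. Siblings may share or split reads, and the shuffles break that link too. The test thus cannot tell shared reads from a shared response. Siblings that moved at least 2-fold in opposite directions made up 379 pairs from 127 subcomponents under heat, 357 pairs from 89 under submergence and 170 pairs from 52 under drought.

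Of the contigs tested, 13605 did not change at least 2-fold under any of the 4 stresses. A change of that size was seen under 1 stress for 7658 contigs, under 2 for 3877, under 3 for 1618 and under 4 for 126.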
